A study of Mus musculus with 4 samples.

How the data were processed

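The data are 4 Affymetrix expression arrays, 1 each for unstimulated and LPS-treated (3 h) bone marrow neutrophils of wild-type and miR-125a-deficient mice. Per the labels, cells were purified with a magnetic bead kit and cultured in medium with serum, total RNA was checked for integrity, and biotin-labelled cRNA was made with a kit that primes at the poly-A tail. According to the series design text, RNA of 3 independent experiments was pooled before hybridisation, so each array averages 3 experiments and the spread between experiments cannot be recovered. Whether the 2 pools of a genotype came from the same experiments is not given in the sources used here. Whether the unstimulated cells were also kept in culture for 3 h is not settled by the labels, which give them as 0 h in one place and as cells without LPS in another.

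The deposited values are log2 signals, 1 per probe set and array, made with MAS5 per the submitters' processing notes; its version and target setting are not given in the sources used here. The unlogged values had a trimmed mean (2% removed at each end) of 500.003 or 500.004 on all 4 arrays, so each array had been scaled to one target before deposit. MAS5 subtracts background and combines the probes of a set on a single array, so dim probe sets scatter widely on the log scale, and between 298 and 428 probe sets per array are listed at 0. Scaling to a common trimmed mean assumes equal overall signal, so a difference shared by most genes would not show. For these arrays no read depth exists, and their number limits the precision.

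Probe sets were named through the platform annotation supplied for the series: of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed, of which 9160 were not among the 64 control probe sets. Entrez identifiers of 34754 probe sets were found in the GRCm38.p6 reference gene table, which changed 0 symbols. That table also gave which genes neighbour each other; no coordinates are given because the build behind the annotation is not given in the sources used here. Probe sets with several symbols or none, and controls, were left out of gene results, which left 18193 genes. Each gene was represented by its probe set with the highest mean log2 value over the 4 arrays.

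In the main setting the deposited scaling was kept, and values under the 60th percentile of all probe sets over the 4 arrays (log2 6.80, signal 111) were set to that floor. A gene was measured in a comparison if it exceeded the floor on at least 1 of its arrays, which held for 9865 genes on any array and 8156 on all 4. Differences are log2 signal of the first group minus the second, called from 2-fold (log2 1). A difference with 1 side at the floor is a lower bound, and bounds enter list medians as such. A difference of 2 differences with a value at the floor is no bound, so no bounds were named for the comparison of responses. Values of further probe sets given for that comparison may still include a signal at the floor. With 1 array per group the comparisons made leave no residual degrees of freedom, so no p-value, standard deviation between arrays or split of samples was computed. An additive model of genotype and LPS would leave 1, by taking any difference between the responses as error, and was not fitted.

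The comparisons were LPS against unstimulated in each genotype, knockout against wild type at each time, the genes called in the same direction at both times, and the difference between the 2 LPS responses. The design, the floor, the 2-fold rule, the 33 gene lists, the rule for named genes and all alternatives except those given here as later were fixed before the data were examined. For each list the median log2 difference was placed among 10000 random lists of the same size drawn from 20 bins of mean signal (seed 1). A list was called below percentile 2.5 or above percentile 97.5; this describes these arrays and is not a test, and over 33 lists and the comparisons made some calls arise by chance. Percentiles were given for lists with at least 5 measured members, a minimum set after the data were seen. Of 548 list symbols 482 were matched, and 409 were above the floor on at least 1 array; the matching of 1 glycolysis symbol was corrected after the data were seen.

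Named genes were, per comparison, the 10 highest and the 10 lowest differences among called genes above the floor on every array of that comparison, the 3 largest lower bounds in each direction, and list members, taking those with the largest differences first. Uncharacterised symbols were passed over in the first 2 parts and counted: 50 and 45 of the LPS calls in wild-type and knockout cells, 7 and 3 of the genotype calls, and 12 of the calls between responses. The lists cover chemokines, cytokines, signalling, effector and housekeeping genes, reported miR-125 targets and markers of cells that a bead-enriched marrow preparation can hold; how many of the marker genes neutrophils themselves express was not analysed here.

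Alternatives were quantile normalization, scaling to a common median over probe sets above the floor on all arrays, the floor at the 50th or 75th percentile, no floor with log2(value + 1), the mean over all probe sets of a gene, leaving out probe sets whose suffix marks shared or cross-hybridising probes, and 10 signal bins for the random lists. Scaling on the 12 probe sets of the Bacillus poly-A controls was added after the data were seen. The planned count of miR-125a seed matches was not run, since no 3′ untranslated sequences were used here.

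Scripts were tested on 4 simulated arrays built from each probe set's mean over all 4 arrays, with normal noise sized from the unstimulated genotype difference. Fold differences were added to the array standing for LPS-treated wild-type cells, whose simulated comparison with unstimulated wild-type cells measured 9377 genes. The 2-fold rule called 2 of 50 genes simulated at 1.5-fold, 48 of 50 at 2.5-fold, 50 of 50 at 4-fold and 50 of 50 at 8-fold, and 25 of 9177 unchanged genes (0.272%). Only genes well above the floor were given a fold difference, so recovery of dim genes was not simulated. Because the noise was taken from a genotype difference, the share of unchanged genes called gives no false-call rate for the genotype comparisons. Of 200 random lists of 15 genes without a shift 13 (6.50%) lay outside the called range, and of 50 lists shifted by 0.5 all 50 did. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.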

Results

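Neutrophils, the short-lived granulocytes that lead the early response to bacteria, were isolated with magnetic beads from the bone marrow of mice carrying or lacking miR-125a, a microRNA. Both genotypes are given as C57BL/6 mice of 8 weeks in the labels. The cells were examined unstimulated and after 3 h with lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that Toll-like receptor 4 recognises. Total RNA from 3 experiments was pooled for each of the 4 groups, and each pool was hybridised to 1 Affymetrix expression array. The 4 groups therefore hold 1 array each, no difference has a replicate check, no test was run, and the number of arrays limits the precision of every value.

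Of 45101 probe sets, 18635 (41.3%) lay above the signal floor on the unstimulated wild-type array, 18726 (41.5%) on the unstimulated knockout array, 17043 (37.8%) on the LPS wild-type array and 17758 (39.4%) on the LPS knockout array. The floor was a log2 signal of 6.80, and 9865 named genes exceeded it on at least 1 array. A gene was called higher or lower where its signal differed at least 2-fold between 2 arrays, and a difference with 1 side at the floor is a lower bound, written as at least N-fold. A gene list was called where its median lay in the lowest or the highest 2.5% of random lists of the same size and signal level. miR-125a itself was not measured here. The probe sets of Spaca6, the gene that hosts it, reached at most a log2 signal of 6.24, under the floor, so the genotype labels could not be checked from these values. Across all probe sets, with values under the floor set to it, the arrays of the 2 genotypes had a correlation of 0.992 unstimulated and 0.991 after LPS. Unstimulated and LPS arrays had correlations from 0.948 to 0.958.

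The first comparison addresses how wild-type neutrophils respond to LPS. Whether unstimulated cells were also cultured for 3 h is open, so LPS differences in either genotype may include an effect of culture. Among genes above the floor on both arrays, the highest differences were those of a transporter, an adhesion molecule and a chemokine. Slc7a11, the cystine transporter that feeds glutathione synthesis, was 72.7-fold higher after LPS, Icam1, an adhesion molecule bound by leukocyte integrins, was 55.5-fold higher, and Cxcl10, an interferon-inducible chemokine, was 53.0-fold higher. Slc7a11 stood near the floor unstimulated (7.02), and its second probe set had a log2 difference of 4.15. The cytokine Il6 was 44.6-fold higher, and the chemokine Ccl5, below the floor in unstimulated cells, was at least 88.0-fold higher. Among the lowest were Klf4, a transcription factor of myeloid differentiation (17.2-fold lower), Prok2, a secreted chemotactic protein (log2 difference -4.09), Ccr2, the receptor of monocyte chemoattractants (14.7-fold lower), and Fos, a subunit of the AP-1 transcription factor (11.1-fold lower). Other probe sets of Ccr2 gave log2 differences of -1.73 and -0.50.

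Other transcripts far higher in wild-type cells included Pim2, a survival kinase, with a log2 difference of 5.01, Adgre1, a macrophage surface receptor gene, with 4.94, and the chemokine Ccl4 with 4.55. Ikbke, a kinase of interferon induction, had 4.48, Sdc4, a cell-surface proteoglycan, had 4.40, and Dusp16, a phosphatase of stress-activated kinases, had 4.39. Smpdl3b, a membrane-bound phosphodiesterase, and Relb, an NF-kB subunit, were at least 41.5-fold and at least 38.7-fold higher. Among the lowest were Atrx, a chromatin remodeller, at -3.60, Ada, adenosine deaminase, at -3.36, Srp54b, a signal recognition particle subunit, at -3.31, and Dock9, a guanine nucleotide exchange factor, at -3.19. Rgs18, a regulator of G-protein signalling, stood at -3.13 and Il18r1, a receptor chain for interleukin-18, at -3.10. The circadian regulator Per2 was at least 16.0-fold lower, the AP-1 subunit Fosb at least 11.3-fold and the phospholipase Gpld1 at least 8.64-fold. Dusp16 had a second probe set at -0.88, and with the probe sets marked as shared or cross-hybridising left out Prok2 stood at -0.94 and Dock9 at -0.97, short of 2-fold. Other probe sets of Atrx ranged from -3.07 to -0.33.

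Cytokine and chemokine genes were higher as groups in wild-type cells. Among CC and other chemokines, 7 of 11 measured genes were higher, 2 were lower and 2 were neither (median log2 difference 2.38, percentile 100 of random lists). Ccl3 had 4.15 and Cxcl16 2.38, while the monocyte attractant Ccl2 was lower at -2.85 and Ccl6 at -1.76. Of 19 inflammatory cytokine genes, 12 were higher, 2 lower and 5 neither (median 2.07, percentile 100). Il1b had 2.62, Tnf 2.94 and the receptor antagonist Il1rn 3.00, and Il1a was at least 31.0-fold and Il10 at least 10.0-fold higher, whereas Csf1 stood at -2.01 and Osm at -1.35. Of the 3 measured chemokines that attract neutrophils, Cxcl2 had 2.02 and Cxcl3 2.49, and Cxcl1 had 0.26 in its brightest probe set and bounds of 1.18 and 1.67 in 2 others.

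The list of NF-kB feedback regulators, which also holds pathway subunits such as Relb, was higher in 10 of 17 and lower in 0 (median 2.18, percentile 100). Nfkbie had 3.40, Tnfaip3, a ubiquitin-editing enzyme, 2.99, and Tnip1, its partner, 4.25. Of 26 interferon-stimulated genes, 18 were higher, 0 lower and 8 neither (median 1.16, percentile 100). Usp18, which removes the modifier ISG15, had 4.34, Oasl1 3.29, Ifit1 3.14 and Rsad2, an antiviral enzyme, 3.01. Of 13 JAK-STAT genes, 4 were higher and 9 neither (median 0.51, percentile 99.3), among them the suppressors Cish at 3.03 and Socs3 at 2.20, and the list call ended with the floor at the 75th percentile (0.40). Toll-like receptor signalling components were higher in 4 of 16 and neither in 12 (median 0.27, not called), with Irak2, a kinase below the receptor, at 2.83 and the co-receptor Cd14 at 1.32.

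Immediate-early and AP-1 factors lay on the other side, with 7 of 18 lower, 2 higher and 9 neither (median -0.65, percentile 0.09). Egr1 stood at -2.29, Jun at -2.19 and Atf3 at -1.84, while Ier3 had 2.01 and Nr4a1 1.75. With the floor at the 75th percentile this median was -0.19 and was not called. MAP kinase phosphatases and RNA-decay regulators split, with 4 of 11 higher, 4 lower and 3 neither (median 0.65). Zfp36l1, an RNA-decay factor, had 2.32, and Dusp1 stood at -1.90 and Dusp6 at -2.12. That median reversed to -0.88 without the shared or cross-hybridising probe sets and was not called in the mean over probe sets (0.33).

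Genes of neutrophil effector functions were counted next. None of 12 secondary and tertiary granule genes was called (median 0.17), Ltf, lactoferrin, having 0.19 and Camp, a cathelicidin, 0.19. Primary granule genes had 1 of 8 lower, Nkg7 at -1.42, and 7 neither (median -0.36, percentile 0.71), with Mpo, myeloperoxidase, at -0.55. Of 10 NADPH oxidase and reactive oxygen genes, 2 were higher, Sod2, the mitochondrial superoxide dismutase, at 3.52 and Hmox1, haem oxygenase, at 2.60 (median 0.52, called). Apoptosis regulators were higher in 7 of 18, lower in 1 and neither in 10 (median 0.39, called), led by the death receptor Fas at 3.72. Bcl2l11, a pro-death BCL2 relative, had 2.20 and Cflar, an inhibitor of caspase-8, 1.65. Both of these calls ended in the mean over probe sets and without shared or cross-hybridising probe sets, and that of the NADPH oxidase list also under quantile normalization and with no floor.

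Of 17 chemoattractant receptor and adhesion genes, 3 were higher, 3 lower and 11 neither (median 0.08, not called), with the integrin Itgal at 1.99, Ccr1 at -1.58 and Cxcr4 at -1.15. Prostaglandin and lipid mediator enzymes were higher in 3 of 9 and neither in 6 (median 0.12), namely Ptges, prostaglandin E synthase, at 3.44, Pla2g7 at 2.92 and Ptgs2, which encodes an inducible cyclooxygenase, 4.01-fold higher. Glycolysis and glucose uptake genes had 0 of 15 called (median -0.03). Mature neutrophil genes were higher in 2 of 14 and lower in 1 (median 0.32), the decoy receptor Il1r2 standing at -2.95 and the Fc receptor Fcgr4 at 1.31. Granulocyte transcription factors had 1 of 14 lower, Irf8 at -1.67 (median 0.36, not called). Cell cycle genes had 1 of 23 lower, Mki67 at -1.15 (median -0.19, percentile 2.16), a call that ended with the floor at the 75th percentile, with no floor, in the mean over probe sets, without shared or cross-hybridising probe sets and with fewer signal bins for the random lists. Genes reported as miR-125 targets were higher in 7 of 30 and lower in 2 (median 0.26, percentile 97.6), and this call ended under quantile normalization, with the floor at the 50th percentile and without shared or cross-hybridising probe sets. Of 2 measured neighbours of the microRNA cluster, Has1, a hyaluronan synthase, was higher with a bound of 1.54 and Fpr2 had 0.24. Housekeeping genes had 0 of 11 called (median 0.21), and ribosomal protein genes had 1 of 24 lower, Rpl12 at -1.09 (median 0.36, not called).

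Markers of other cell types also differed between the wild-type arrays. Monocyte and macrophage markers were higher in 5 of 12 and lower in 2 (median 0.67, percentile 99.9), with Csf1r at 2.64, Vcam1 at 3.13 and F13a1 at -1.93. The median was -0.04 with no floor, and 0.20 and 0.15 and not called with the floor at the 50th and 75th percentiles, and without shared or cross-hybridising probe sets the call ended too (0.43). Dendritic cell and MHC class II genes were higher in 2 of 9 and lower in 2 (median 0.29, not called). Erythroid markers had 1 of 7 lower (median -0.80, percentile 2.48), a call that ended on the poly-A scale and with fewer signal bins. Platelet markers were higher in 1 of 5 and lower in 1, eosinophil, basophil and mast cell markers lower in 1 of 7, stem and progenitor markers lower in 1 of 6, and stroma and endothelium markers lower in 1 of 3. None of 7 plasma cell, 3 B cell and 2 T and NK cell markers was called.

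In all, 693 of 9507 measured genes were higher in wild-type cells after LPS and 921 were lower, of which 106 and 136 were lower bounds. Differences of at least 4-fold numbered 200 higher and 111 lower. The balance depended on the scaling of the arrays: 835 were higher and 707 lower under quantile normalization, 856 and 730 under median scaling, and 348 and 2271 with the arrays scaled on their poly-A spike-in controls. These scalings moved the median difference of all genes by 0.10, 0.14 and -0.54. Relative to the shifted median of all genes, the JAK-STAT, NADPH oxidase, apoptosis and miR-125 target lists, whose medians turned negative on the poly-A scale, lay in the highest 2.5% of random lists. That scaling shifts listed and random genes alike, so apart from values at the floor their placement could hardly change and is no check of these calls. A further 9 medians that were not called also changed sign on that scale.

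The same question was asked of knockout neutrophils. The highest differences among genes above the floor on both arrays were those of Cxcl10 (46.3-fold), Fas (42.2-fold), Adgre1 (35.7-fold), Icam1 (34.8-fold) and Slc7a11 (34.1-fold). The second probe set of Slc7a11 had a log2 difference of 3.86, against 4.15 in wild-type cells. Ccl5 was at least 94.1-fold and Il6 at least 67.5-fold higher, both from below the floor. Klf4 was 20.4-fold, Prok2 15.3-fold, Per2 14.4-fold and Ccr2 11.6-fold lower. Other probe sets of Ccr2 ranged from -1.64 to -0.34. In this genotype 634 of 9578 measured genes were higher and 765 lower, of which 90 and 118 were lower bounds, and 187 and 69 reached 4-fold. The split was 735 higher and 633 lower under quantile normalization, 750 and 623 under median scaling, and 324 and 2385 on the poly-A scale, and the shifts of the median of all genes were 0.08, 0.11 and -0.57.

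Usp18 had a log2 difference of 4.92 in knockout cells, Ccl4 4.89, Relb 4.84, Ccl3 4.77 and Ikbke 4.40, and Smpdl3b was at least 45.8-fold higher. On the low side were Il18r1 at -3.27, Ada at -3.22, Foxd4, a forkhead factor, at -3.17, Il1r2 at -3.05, Rgs2, a regulator of G-protein signalling, at -2.97 and Atrx at -2.84. Other probe sets ranged from -3.34 to -0.08 for Rgs2 and from -2.48 to -0.05 for Atrx. Fosb was at least 8.74-fold, Car1, an erythroid carbonic anhydrase, at least 8.36-fold and Gpld1 at least 7.61-fold lower.

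The gene lists were counted in knockout cells in the same way. CC and other chemokines had 7 of 10 higher and 1 lower (median 2.30), inflammatory cytokines 12 of 18 higher and 2 lower (2.07), NF-kB feedback regulators 10 of 17 higher (1.85) and interferon-stimulated genes 18 of 26 higher (1.41), all at percentile 100. Ifit1 had 4.11, Oasl1 3.97 and Rsad2 3.65. All 3 neutrophil-attracting chemokines were higher, Cxcl1 with 2.27, Cxcl2 with 2.75 and Cxcl3 with 1.74. Immediate-early factors had 2 of 18 higher and 4 lower (median -0.34, percentile 3.6, not called, but called with the floor at the 50th percentile, with no floor, without shared or cross-hybridising probe sets and with fewer signal bins), with Fos at -2.66 and Egr1 at -0.83. Apoptosis regulators had 5 of 18 higher and 1 lower (0.37, called except with the floor at the 75th percentile, in the mean over probe sets and without shared or cross-hybridising probe sets), and primary granule genes 1 of 8 lower (-0.47, called). Cell cycle genes had 0 of 23 called and a median of -0.22, a list call kept only under median scaling, with the floor at the 50th percentile and on the poly-A scale. JAK-STAT genes had 5 of 14 higher (0.29), NADPH oxidase genes 2 of 10 higher (0.40), Toll-like receptor components 3 of 16 higher (0.19), MAP kinase phosphatases 4 of 12 higher and 4 lower (0.22), and miR-125 targets 5 of 30 higher and 1 lower (0.03), with none of these lists called; the JAK-STAT list was called under quantile normalization, median scaling and in the mean over probe sets, and the NADPH oxidase list in that mean and with no floor. Among cell type markers, erythroid genes had 5 of 7 lower (median -1.38, percentile 0), monocyte and macrophage genes 5 of 13 higher and 2 lower (0.45, called except with no floor), and dendritic cell and MHC class II genes 2 of 9 higher (0.49, called except with the floor at the 75th percentile and without shared or cross-hybridising probe sets). Those last 2 medians and that of apoptosis regulators were -0.10, -0.06 and -0.20 on the poly-A scale, below 0 but in the highest 2.5% of random lists, which shift with them. A further 10 medians that were not called changed sign on that scale too.

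**Figure D1:**
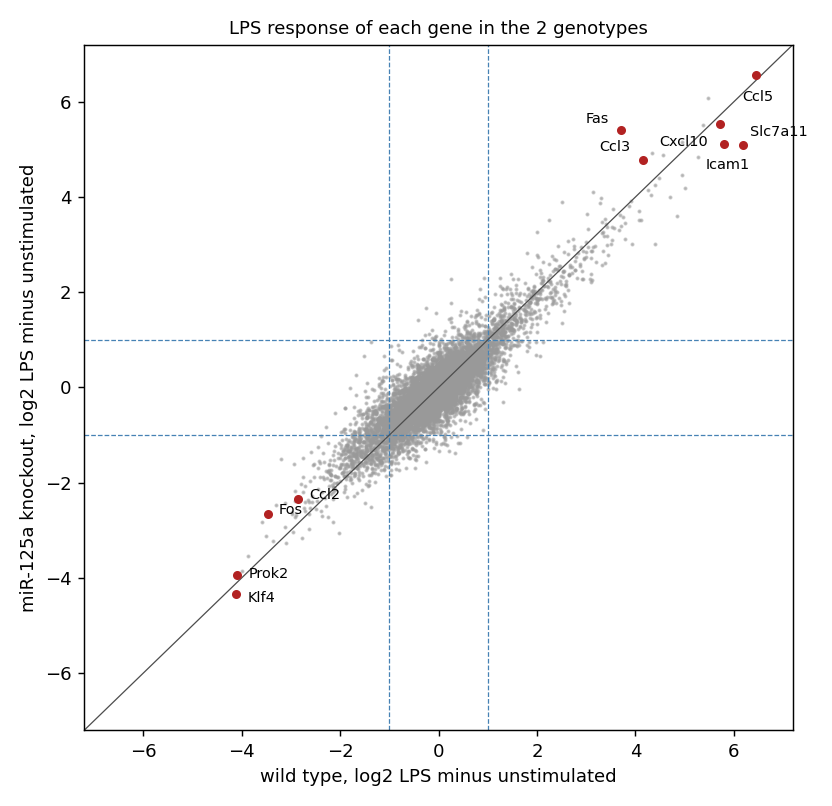
LPS response of each of 9220 genes measured in both genotypes, as log2 signal after LPS minus unstimulated, in wild-type cells on the horizontal axis and knockout cells on the vertical axis; dashed lines mark 2-fold, the solid line equal responses, and values with 1 side at the floor are lower bounds. Points follow the line of equal responses with a correlation of 0.892 across genes, while Fas lies above it (3.72 in wild-type and 5.40 in knockout cells).

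Gene by gene, the 2 responses ran together. Across the 9220 genes measured in both genotypes, the LPS differences had a Pearson correlation of 0.892 and a Spearman correlation of 0.832; genes are not independent replicates. The 2 responses share no array. Klf4, Prok2 and Ccr2 were among 543 genes lower in both genotypes, and Icam1, Cxcl10 and Slc7a11 among 514 higher in both, where independent lists of these sizes would share 76.3 and 47.3. No gene was higher in one genotype and lower in the other, and of 1949 genes called in either, 97.6% had the same sign.

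The next comparison asks what the loss of miR-125a alters in unstimulated cells. Few genes reached 2-fold. Lipg, which encodes endothelial lipase, was 4.49-fold lower in the knockout, Hs3st2, a heparan sulfate sulfotransferase, 4.22-fold, Fas 3.21-fold and Mcpt8, a basophil protease, 3.06-fold, and Olfml2b, an extracellular matrix protein, was at least 7.85-fold lower. Dnah8, an axonemal dynein heavy chain, was 3.27-fold higher, Trim34a, of the tripartite motif family, 2.79-fold and Acvrl1, a receptor of the TGF-beta superfamily, 2.44-fold. Of 9401 measured genes 33 were higher and 62 lower (1.01%), 3 and 17 of them as lower bounds, and the median absolute log2 difference was 0.16 against 0.42 for LPS in wild-type cells. On the poly-A scale, which moved the median of all genes by 0.11, 78 were higher and 52 lower.

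Further genes higher in unstimulated knockout cells were Igkv4-72, an immunoglobulin kappa variable gene, with 1.65, Aunip, an Aurora kinase partner, with 1.62, Dusp16 with 1.37, Lgalsl with 1.35, Gstm3, a glutathione transferase, with 1.23, Taf4b, a transcription initiation factor subunit, with 1.18 and Kcnj11, a potassium channel, with 1.16. Apoc2, an apolipoprotein, was at least 2.69-fold, the amino acid transporter Slc1a5 at least 2.38-fold and Ptprcap at least 2.34-fold higher. Lower were Dock9 at -1.77, Tbrg3 at -1.67, Adat2, a tRNA-editing deaminase subunit, at -1.63, Zdhhc12, a palmitoyltransferase, at -1.62, Dsp, the desmosomal protein desmoplakin, at -1.61 and Zap70, a T cell kinase, at -1.55. Dubr was at least 3.52-fold and Casp14 at least 2.81-fold lower. Other probe sets opposed Trim34a (-0.65) and Dusp16 (-0.27) and both other probe sets of Lipg lay below 0 too, 1 of them with a bound of -1.94. Hs3st2 and Casp14 were read from probe sets marked as cross-hybridising. Averaged over probe sets, Dnah8, Acvrl1, Hs3st2, Zap70, Gstm3, Taf4b, Kcnj11, Casp14, Slc1a5, Dock9 and Dsp were under 2-fold, and with the floor at the 75th percentile so were Fas, Mcpt8, Igkv4-72, Aunip, Lgalsl, Tbrg3 and Dubr. For Dnah8, Hs3st2, Zap70, Gstm3, Kcnj11 and Casp14 no other probe set was measured, so averaging only added values at the floor.

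Several gene lists had medians outside the range of random lists in unstimulated cells. Immediate-early and AP-1 factors had 1 of 18 called lower, Egr1 at -1.13, but 17 of 18 below 0 (median -0.32, percentile 0), among them Egr3 at -0.73 and Fos at -0.49. CC and other chemokines had 0 of 7 called and a median of -0.32 (percentile 0.13), with Ccl2 at -0.56 and Ccl3 at -0.54. Interferon-stimulated genes had 0 of 25 called, 16 below 0 and 9 above, and a median of -0.19 (percentile 0.03), with Oasl1 at -0.85 and Ifit1 at -0.59. In their brightest probe sets all 3 neutrophil-attracting chemokines lay below 0, Cxcl1 being lower at -1.14 in a probe set marked as cross-hybridising, but its other probe sets did not show this, 1 having 0.077 and 1 lying under the floor on both arrays. JAK-STAT genes (median -0.14, 7 of 12 below 0) and ribosomal protein genes (0.11) were called, but these medians turned to 0.05 and -0.03 without shared or cross-hybridising probe sets, and the call of mature neutrophil genes (0.12) ended under quantile normalization (0.03) and without those probe sets. Apoptosis regulators had Fas alone called among 17 (median -0.05). NF-kB feedback regulators (median 0.07), inflammatory cytokines (-0.10), Toll-like receptor components (-0.09), secondary and tertiary granule genes (0.11) and miR-125 targets (0.01) held 0 called genes each and were not called, although the NF-kB list was called in the mean over probe sets (0.13) and without shared or cross-hybridising probe sets (0.16).

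Markers of other cell types differed between the unstimulated arrays as well. Eosinophil, basophil and mast cell markers had 4 of 6 lower and 6 of 6 below 0 (median -1.09, percentile 0): Mcpt8 at -1.61, the eosinophil peroxidase gene Epx at -1.44, the eosinophil granule gene Prg2 at -1.10 and Cpa3, a mast cell protease, as a bound of -1.08. Erythroid markers lay above 0 in 7 of 8 with 0 called (median 0.53, percentile 100), Slc4a1, the red cell anion exchanger, having 0.87. Plasma cell markers had a median of 0.24 with 0 of 7 called, and the list call ended under quantile normalization, with the floor at the 50th percentile, with no floor, in the mean over probe sets and on the poly-A scale. The monocyte and macrophage median was 0.01.

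The genotype comparison was repeated on LPS-treated cells. Ctse, the aspartic protease cathepsin E, was 4.59-fold lower in the knockout, Lipg 3.83-fold, Adat2 3.26-fold and Dynlt1f, a dynein light chain, 3.18-fold, and Olfml2b was at least 7.80-fold lower. Rab3a, a GTPase of regulated exocytosis, was 3.94-fold higher, Trim5, of the tripartite motif family, 3.31-fold and Zfp593, a zinc-finger protein, 2.98-fold. Of 9262 measured genes 57 were higher and 58 lower (1.24%), of which 12 and 13 were lower bounds. Quantile normalization gave 47 higher and 76 lower, and the poly-A scale 62 and 36.

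Igkv4-72 had 1.53 in this comparison, Plekhg1 1.49, Lactb2, a mitochondrial nuclease, 1.45, Igkv4-68 1.45, Ifi202b, an interferon-inducible gene, 1.41, Zfp429 1.38 and Dnah8 1.35. Zdhhc14 was at least 3.50-fold, Fam71b at least 3.28-fold and Nrxn3 at least 2.85-fold higher. Lower were Dsp at -1.66, Arhgap31, a GTPase-activating protein, at -1.62, Mcpt8 at -1.48, Gbp2b, an interferon-inducible GTPase, at -1.46, Rps27, a ribosomal protein gene, at -1.40 and Ifi204, an interferon-inducible DNA sensor, at -1.39. St6galnac1 was at least 3.83-fold and Ifi44l at least 2.74-fold lower. Second probe sets of Ctse (0.10), Rab3a (0.04), Lactb2 (0.04), Arhgap31 (-0.21) and Ifi44l (-0.31) showed little difference, and other probe sets of Lipg gave -2.34 and a bound of -0.30. Rab3a, Zfp593, Igkv4-68, Dynlt1f and Zdhhc14 were read from probe sets marked as cross-hybridising. Under the floor at the 75th percentile Trim5, Igkv4-72, Igkv4-68, Zfp429, Mcpt8, Gbp2b, Rps27, Ifi204, Zdhhc14 and St6galnac1 were under 2-fold, and in the mean over probe sets so were Zfp593, Dnah8, Dsp and Nrxn3. For Zfp593, Dnah8 and Nrxn3 no other probe set was measured, so that mean only added values at the floor.

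None of the inflammatory lists was called between genotypes after LPS. Chemokines (median 0.02), inflammatory cytokines (0.03), NF-kB feedback regulators (-0.10), interferon-stimulated genes (0.12) and immediate-early factors (-0.11) lay inside the range of random lists, although Cxcl3 was lower at -1.20 and Ifi204 was the 1 interferon-stimulated gene called of 26. The interferon list was called under quantile normalization (0.10), with the floor at the 75th percentile (0.19), with no floor (0.18) and in the mean over probe sets (0.11), and the immediate-early list with no floor (-0.16). Il6 had 0.48, Tnf -0.22 and Il1b 0.22. Genes reported as miR-125 targets had 0 of 29 called, 21 below 0 and 8 above (median -0.18, percentile 0.37), with Bmf at -0.60, Bbc3 at -0.57 and Tnfaip3 at -0.02. That list call ended in the mean over probe sets and without shared or cross-hybridising probe sets, with a median of -0.09 in each. Secondary and tertiary granule genes had a median of 0.14 (0 of 12 called, list called), which turned to -0.03 under quantile normalization and was not called without shared or cross-hybridising probe sets, and ribosomal protein genes a median of 0.09 (0 of 24 called, list called), a call that ended under quantile normalization, in the mean over probe sets and without those probe sets. Eosinophil, basophil and mast cell markers again had 6 of 6 below 0 and 2 lower, Mcpt8 and Prg2 (median -0.84, percentile 0).

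**Figure D2:**
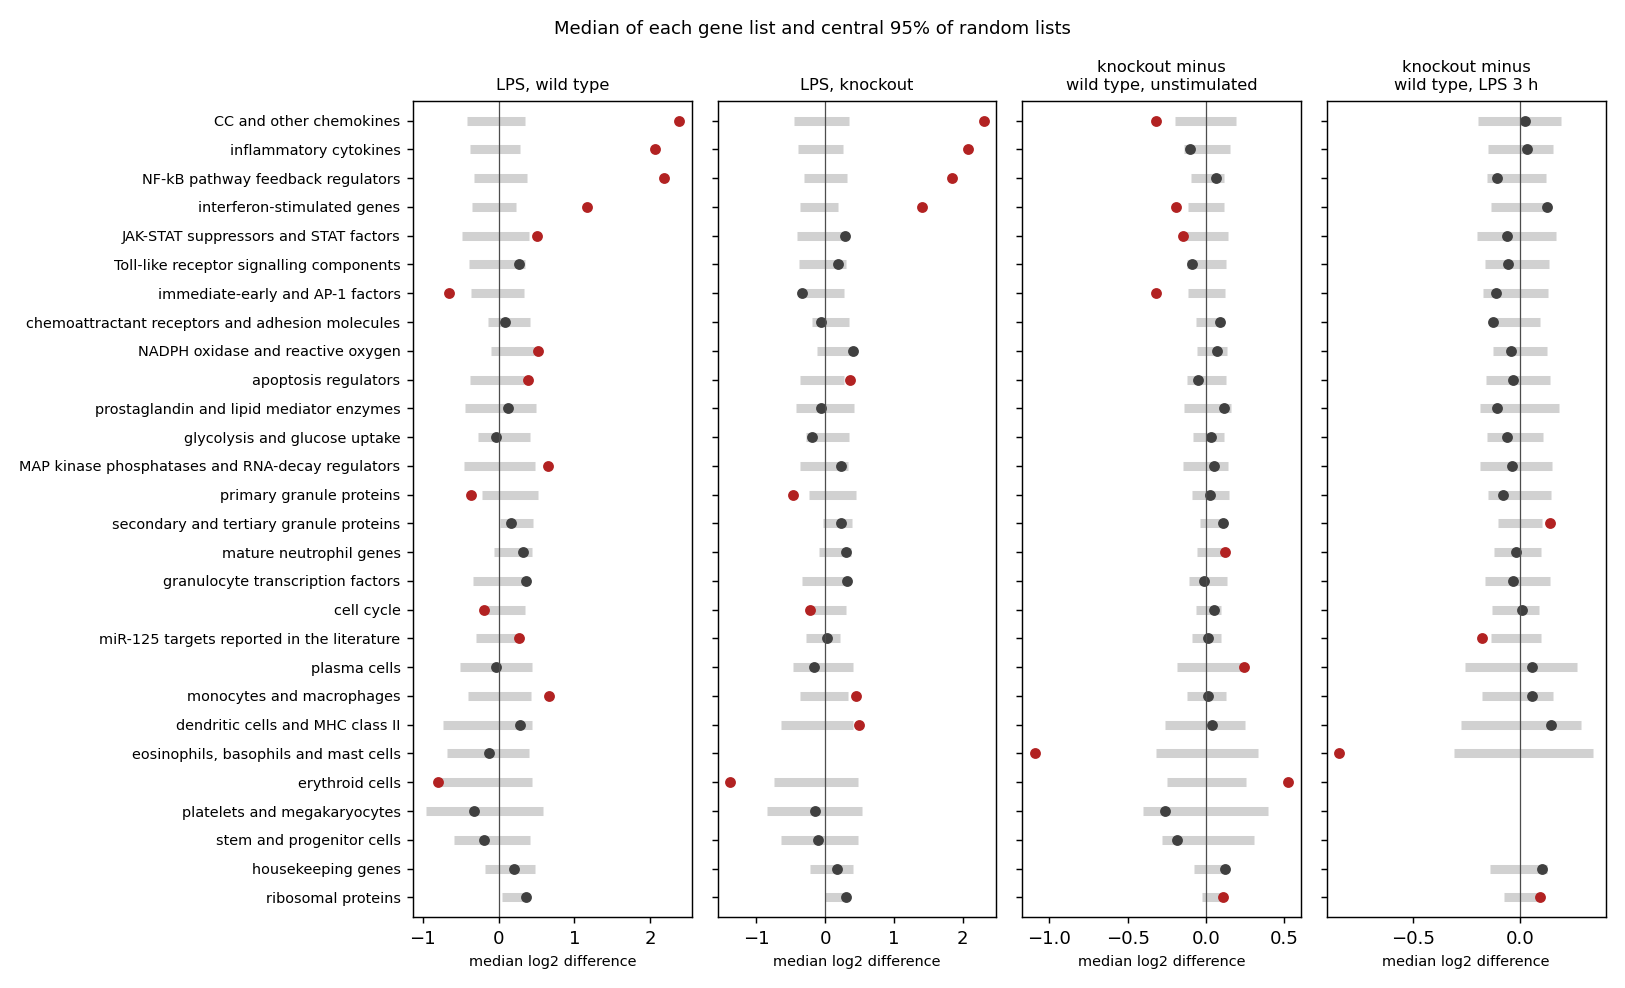
Median log2 difference of each gene list with at least 5 measured members (points) in the 4 comparisons, with grey bars over the range of random lists matched on signal that leaves out 2.5% at each end and red points for medians outside the bar. Chemokines, cytokines, NF-kB regulators and interferon-stimulated genes lie far to the right after LPS in both genotypes (medians 1.16 to 2.38), and eosinophil, basophil and mast cell markers lie to the left in both genotype comparisons (-1.09 and -0.84).

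The unstimulated and LPS genotype differences rest on separate arrays, but whether the pools of both times came from the same cell preparations is not given in the sources used here, so a difference between preparations would also show at both. Lipg, Olfml2b, Adat2, Dsp, Mcpt8, Zap70, Gbp2b, the eosinophil granule gene Prg2, the kinase Riok2, the collagen gene Col5a1 and the leukocyte receptor Cd84 were among 19 genes lower in the knockout at both times. Dnah8, Trim34a, Trim12a, Glo1, which detoxifies methylglyoxal, Acvrl1, Zfp593, Plekhg1, Ppp5c, Slc9a3r2 and Igkv4-72 were the 10 genes higher at both. Independent lists of these sizes would share 0.36 lower and 0.17 higher, a value that leaves shared preparations out. Ammecr1 was the 1 gene called in opposite directions. Across 8798 genes measured at both times the 2 genotype differences had a Pearson correlation of 0.281 and a Spearman correlation of 0.204. The 29 genes included 22 above the floor on every array, and 3, Adat2, Lipg and Olfml2b, were called at both times under every setting tried. The largest difference belonged to BC018473, an uncharacterised name outside the rule for named genes and chosen after its values were seen: its log2 signal was 9.88 and 14.08 in wild-type cells and under the floor in the knockout at both times, at least 8.45-fold and at least 156-fold lower. These values rest on a single probe set, whose suffix marks shared or cross-hybridising probes. The other probe set of BC018473 lay under the floor on all 4 arrays, with 1.57 in LPS-treated wild-type cells.

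**Figure D3:**
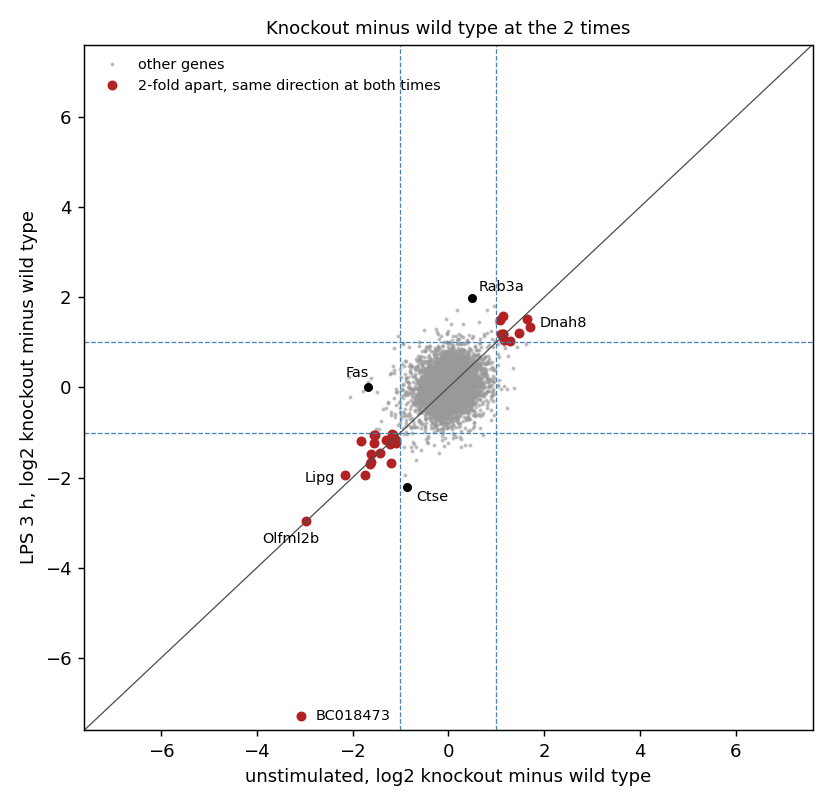
Log2 signal of knockout minus wild type for 8798 genes measured at both times, unstimulated on the horizontal axis and after LPS on the vertical axis; dashed lines mark 2-fold, the solid line equal differences, red points the 29 genes called in the same direction at both times, black points 3 genes called at 1 time, and values with 1 side at the floor are lower bounds. Olfml2b (-2.97 and -2.96) and Lipg (-2.17 and -1.94) lie along the line, while Fas (-1.68 unstimulated), Ctse (-2.20 after LPS) and Rab3a (1.98 after LPS) were called at 1 time only.

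The last comparison asks whether the LPS response differed between genotypes, as the knockout response minus the wild-type response. Fas had a difference of 1.68, with log2 signals of 8.87 and 7.19 in unstimulated wild-type and knockout cells and 12.59 in both after LPS. Hs3st2 had 2.31, Ammecr1 2.18, the chemokine Cxcl1 2.01, Mpp5, a cell polarity scaffold, 1.92 and Zdhhc12 1.83. The values of Hs3st2 and Cxcl1 come from probe sets marked as cross-hybridising. At the other end were Lsm7, an RNA-binding protein of the decay and splicing machinery, at -1.79, Gstm3 at -1.68, Hps5, of lysosome-related organelle formation, at -1.62 and the heat shock gene Hspa1b at -1.61. Of 9865 genes 121 were higher and 86 lower by 2-fold, 82 and 53 of them above the floor on all arrays. The split was 92 and 117 under quantile normalization and 98 and 106 on the poly-A scale.

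Ttyh3, a membrane protein of the tweety family, had 1.56, Agap3 2.83-fold, Rab3a 1.49 and Spopl 1.48, and Slc41a3 stood at -1.60, the import receptor Ipo4 at -1.56, the endolysosomal channel Tpcn1 at -1.56, Med25, a Mediator subunit, at -1.42, Acp5, an acid phosphatase, at -1.41 and Rad54l2 at -1.39. Other probe sets gave -1.67 and -1.63 for Hspa1b, but 0.09 and 0.91 for Cxcl1, 0.11 for Mpp5, 0.86 for Slc41a3 and 0.55 for Rad54l2. They also gave -0.71 and 0.28 for Spopl, 0.04 for Rab3a, -0.65 for Ipo4 and -0.22 for Med25. Both further Cxcl1 values include unstimulated signals at the floor, so they do not measure a difference between responses. The Rab3a value is the same as that of its genotype difference after LPS. With the floor at the 75th percentile Fas (0.33), Hs3st2 (0.73), Ammecr1 (0.22), Gstm3 (-0.18), Hps5 (-0.60), Acp5 (-0.44), Ipo4 (-0.23) and Ttyh3 (0.92) were under 2-fold, and so were Agap3 (0.75), Spopl (0.35), Tpcn1 (-0.52) and Med25 (-0.82) in the mean over probe sets. For Agap3 and Tpcn1 no other probe set was measured, so that mean only added values at the floor.

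By group, immediate-early and AP-1 factors had a median of 0.25 (percentile 99.9), 13 of 18 above 0, with Egr1 higher at 1.46; with no floor the median was 0.09 and not called. Interferon-stimulated genes had a median of 0.22 (percentile 99.6), 17 of 26 above 0 and 0 called, with Ifit1 at 0.97 and Gbp2 at 0.82, and the call ended without shared or cross-hybridising probe sets (0.18). NF-kB feedback regulators had a median of -0.19 (percentile 1.29), 13 of 17 below 0 and 0 called, with Zc3h12a, an RNA-decay enzyme, at -0.72, and this call ended under quantile normalization (-0.15), with the floor at the 75th percentile and in the mean over probe sets. Erythroid markers had a median of -0.40 (percentile 1.29), 6 of 8 below 0 and 0 called, and with the floor at the 50th percentile (-0.25) or no floor the list was not called. Each of these values contains the unstimulated genotype difference with its sign turned, in which the immediate-early and interferon-stimulated lists lay below 0 and the erythroid list above 0.

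Separate probe sets of a gene measure how far a difference stands above hybridisation noise within these arrays. Across genes with 2 measured probe sets, the correlation of their differences was 0.70 for LPS in wild-type cells, 0.71 in knockout cells, 0.25 for genotype unstimulated, 0.30 for genotype after LPS and 0.22 for the difference between responses. A second probe set had the same sign for 92.9% of the called LPS differences in wild-type cells, 93.8% in knockout cells, 75.9% and 71.1% of the genotype differences, and 69.2% of the differences between responses. It was itself 2-fold apart in the same direction for 440 of 780 called LPS differences in wild-type cells and 355 of 658 in knockout cells, but for 6 of 29 and 7 of 38 genotype differences and 6 of 78 differences between responses.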

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

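The tests of explanations given here were chosen only after the patterns were seen, as was scaling on the poly-A controls; the test on further eosinophil, basophil and mast cell markers was written before the values of those markers were seen.

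Ammecr1 was the only gene called in opposite directions by genotype at the 2 times: its signal was lower in the knockout unstimulated (-1.04) and higher after LPS (1.14), a difference between responses of 2.18 that was not tested. The 12 poly-A control probe sets, spiked-in bacterial transcripts outside the gene comparisons, all gave higher signal on the LPS arrays, by a mean log2 difference of 0.54 in wild-type and 0.57 in knockout pools. Among 9160 probe sets without a gene name here, 14 were called by genotype in the same direction at both times, 9 higher and 5 lower, and 1 in opposite directions.

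The first pattern is the 29 genes called by genotype in the same direction at both times, on separate arrays, although the pools of both times may come from the same cell preparations, whose differences would then show at both. Noise of single arrays is argued against for these 29, since it would give as many genes in opposite directions and there was 1, against 7 beside 37 with the floor at the 50th percentile, and with no floor, where dim genes enter, 826 beside 886. DNA of another strain carried along with the knocked-out locus may account for part of the set: 5 of the 29 lie on the chromosome of Mir125a (random lists gave 1.60 on average, and this count lay at percentile 98.9). Riok2, Dynlt1f and Slc9a3r2 have 0, 25 and 38 measured genes in between, and Glo1 and Dnah8 lie farther off with 129 and 131. Dynlt1f was read from a probe set marked as cross-hybridising. Glo1 and Dnah8 lie within 20 measured genes of each other and may not be independent entries in that count, which the random lists do not allow for. The other 24 lie on other chromosomes, which that explanation does not reach. For those 24, strain segments elsewhere cannot be told apart from other causes, because 3 pairs of near neighbours were found (Cd84 with Olfml2b, Ncmap with Zfp593, Trim12a with Trim34a) against 1.29 in random lists, percentile 91.2. A sequence variant under a single probe set is argued against for 5 of 10 genes with another measured probe set, Acvrl1, Col5a1, Dsp, Glo1 and Lipg, where another was at least 0.58 apart in the same direction at both times, but for the other 5, Ppp5c and Trim34a with opposed probe sets (-0.36 after LPS and -0.65 unstimulated) and Riok2, Slc9a3r2 and Trim12a with smaller differences at 1 time or both, and for the 19 genes without another, it cannot be told apart from a difference in level; an effect of losing miR-125a itself stays open as untested.

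The second pattern is the lower signal of eosinophil, basophil and mast cell markers in the knockout. A smaller share of these cells in the knockout pools cannot be told apart from lower transcript levels within them, because in pooled RNA both lower the markers. Only 3 of 19 further markers were measured (median -0.46), too few to be placed among random lists. Rnase2a had -1.01, Alox15 a bound of -0.46 and Slc18a2 0.24. Prg2 had log2 signals of 11.42 in wild-type and 10.32 in knockout cells unstimulated, Mcpt8 9.01 and 7.40, and the bead kit is meant to remove such cells. A purer knockout preparation, with fewer cells of every other type, is argued against only for erythroid cells. Their markers lay above 0 in 7 of 8 with a median of 0.53 unstimulated, and more erythroid cells in the knockout pools stay open. B cell (-0.11), T and NK cell (-0.28), platelet (-0.26) and stem and progenitor (-0.18) medians lay below 0, so fewer of those cells cannot be excluded. Scaling of the arrays is argued against too, because the list median stayed at -0.60 or lower under all 4 scalings. Whether miR-125a loss alters the number of these cells or their transcripts was not tested.

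The third pattern is that more genes were lower than higher after LPS. Scaling of the arrays cannot be told apart from a true excess, because a common factor moves the balance and the scalings disagree: the ratio of lower to higher genes was 1.33 in wild-type and 1.21 in knockout cells as deposited, at most 0.853 under median scaling, and 6.53 and 7.36 on the poly-A scale. Less messenger RNA per total RNA in the LPS pools cannot be told apart from a technical difference, because the poly-A controls were at least 0.54 higher on the LPS arrays while the hybridisation controls, added after labelling, were also higher by 0.26 or more. Probe sets of 18S ribosomal RNA were higher too, by 0.71 in wild-type and 0.85 in knockout pools, which goes with that explanation. Control probe sets of 2 messenger RNAs also rose, by less: beta-actin by 0.18 and 0.29 and Gapdh by 0.21 and 0.12. The 18S rise therefore does not decide between the explanations. A true excess of lower transcripts stays open as untested. It may be a response to LPS or, if the unstimulated cells were not cultured, to culture for 3 h.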

How the results depend on the processing

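Scaling on the poly-A controls was chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group has 1 array, its replicate number comes from no label, and which experiments entered which pool is not given in the sources used here. The seed-match count was not run under any setting, whole or for 8-base matches, since no 3′ untranslated sequences were used here, and the correlation of separate probe sets has no value in the mean over probe sets. Among gene list medians under the alternatives, 984 kept their sign and their call or its absence, 108 that were not called changed sign without gaining a call (34 on the poly-A scale, 23 under quantile normalization), 33 gained a call, 59 lost it and 13 called ones reversed; among named genes 1103 were the same, 126 dropped under 2-fold and 4 reversed. Where a count moved with the floor or the mean over probe sets, the construction shows part of the cause, since a higher floor tests fewer dim genes and no floor admits all of them; for the other values the cause was not tested unless one is given. Low signal over background limits the genotype differences: genes under a mean log2 of 8 had a median absolute genotype difference of 0.24 unstimulated, against 0.10 for those over 12.

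With no floor, LPS calls were 2563 higher and 3160 lower in wild-type and 2665 and 2919 in knockout cells, genotype calls 2016 and 1705 unstimulated and 2307 and 1790 after LPS, calls between responses 2871 and 2656, and same-direction genotype calls 535 and 351. The correlation of the LPS responses was then 0.312 (0.892 in the main setting), and those of separate probe sets 0.269 and 0.226 for LPS, 0.029 and 0.028 for genotype, and 0.026 between responses. With the floor at the 50th percentile, genotype calls were 77 and 105 unstimulated and 138 and 118 after LPS, and calls between responses 269 and 223. With the floor at the 75th percentile, 528 genes were lower after LPS in wild-type and 412 in knockout cells, genotype calls were 11 and 17 unstimulated and 16 and 24 after LPS, calls between responses 25 and 21, same-direction calls 4 higher and 9 lower, and the probe set correlations 0.419 for genotype after LPS and 0.333 between responses. In the mean over probe sets, 505 genes were lower after LPS in knockout cells, genotype calls were 15 and 37 unstimulated and 28 and 31 after LPS, calls between responses 57 and 35, and 3 same-direction genes were higher. On the poly-A scale, LPS calls were 348 and 2271 in wild-type and 324 and 2385 in knockout cells, 78 genes were higher by genotype unstimulated, 36 lower by genotype after LPS, and 17 higher and 12 lower at both times. Without shared or cross-hybridising probe sets, 5 same-direction genes were higher.

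Called medians that reversed on the poly-A scale were JAK-STAT genes (-0.025), NADPH oxidase genes (-0.018), apoptosis regulators (-0.15) and miR-125 targets (-0.27) for LPS in wild-type cells, apoptosis regulators (-0.20), monocyte and macrophage markers (-0.10) and dendritic cell and MHC class II genes (-0.063) for LPS in knockout cells, where the shift of all genes by that scaling shows the cause, and JAK-STAT genes (0.0074) for genotype unstimulated, where the cause was not tested. Without shared or cross-hybridising probe sets, MAP kinase phosphatases and RNA-decay regulators reversed for LPS in wild-type cells (-0.88, the value of Dusp16, which reversed with it), as did JAK-STAT (0.050) and ribosomal protein genes (-0.026) for genotype unstimulated, Dusp16 (-0.27) and Trim34a (-0.65) for genotype unstimulated and Ppp5c (-0.26) for genotype after LPS, each then read from another probe set or fewer genes. Monocyte and macrophage markers for LPS in wild-type cells reversed with no floor (-0.045), and secondary and tertiary granule genes for genotype after LPS under quantile normalization (-0.029); the cause was not tested.

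The 29 same-direction genes numbered 28 under quantile normalization (25 of them shared), 31 under median scaling (29 shared), 37 and 13 with the lower and higher floor (29 and 13 shared), 16 in the mean over probe sets (14 shared), 19 without shared or cross-hybridising probe sets (17 shared) and 29 on the poly-A scale (22 shared). Genes in opposite directions numbered 1 in the main setting, 7 and 0 with the lower and higher floor, 826 with no floor, 2 without shared or cross-hybridising probe sets, 1 under median scaling and 0 under quantile normalization, in the mean over probe sets and on the poly-A scale.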

Other observations

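The gene families described here, from 12 examined, were chosen after the data were seen, and no explanation was tested for them. Interferon-inducible GTPases of the Gbp and Irg families, which attack the vacuoles of intracellular pathogens, were higher after LPS in 5 of 7 measured members in wild-type and 4 of 7 in knockout cells, with list medians of 1.12 and 1.70 that stayed above 0 under all 4 scalings. On the poly-A scale 2 of 7 were higher in wild-type and 4 in knockout cells, and under quantile normalization 5 and 6. Irgm2 had log2 differences of 3.55 and 3.75 and Irgm1 2.77 and 2.46, while Gbp7 was lower in wild-type cells at -1.58 and stood at -0.59 in knockout cells. Among solute carriers, 17 were higher and 11 lower in wild-type and 15 and 13 in knockout cells, a balance that depended on the scaling: 20 and 6 in wild-type and 15 and 11 in knockout cells under quantile normalization, and 8 and 41 and 8 and 40 on the poly-A scale. The glucose transporter relative Slc2a6 had 3.51 and 3.02, the aromatic amino acid transporter Slc16a10 2.96 and 2.71, and the peptide and histidine transporter Slc15a3 2.40 and 2.20, whereas the lactate transporter Slc16a1 stood at -2.28 and -2.49. Splicing factors had 0 of 32 higher and 5 lower in wild-type and 6 lower in knockout cells, among them Prpf39 (-1.77 and -1.30), Srsf10 (-1.53 and -1.46) and Srek1 (-1.49 and -2.43), and 11 and 13 lower on the poly-A scale. Their medians of -0.08 and -0.11 were small, and the wild-type one was 0.06 under median scaling.

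Neighbouring Trim genes, some of which encode antiviral factors, were compared as deposited. Of the 7 measured genes of the group around Trim12a, 6 had positive differences at both times: Trim34a (1.48 unstimulated, 1.20 after LPS), Trim12a (1.13, 1.18), Trim30d (0.91, 1.08), Trim5 (0.80, 1.73), Trim21 (0.33, 0.51) and Trim30a (0.22, 0.44). Trim12c had -0.20 and 0.04. Trim34a and Trim12a were already among the genes called higher at both times, so the count of 6 is not independent of those calls. A second probe set of Trim34a opposed the unstimulated difference (-0.65). That of Trim12a, above the floor on 2 arrays, gave only bounds of 0.13 unstimulated and 0.18 after LPS.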
